A study of Mus musculus with 10 samples.

How the data were processed

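Chromatin accessibility was measured by ATAC-seq (assay for transposase-accessible chromatin with sequencing), in which a transposase cuts and tags open DNA, in progenitor cells sorted from the bone marrow of C57BL/6 mice. The 10 libraries fell into 5 groups of 2 replicates: wild-type long-term hematopoietic stem cells (LT-HSC), wild-type lymphoid-primed multipotent progenitors (LMPP), wild-type monocyte-dendritic cell progenitors (MDP), wild-type common dendritic cell progenitors (CDP), and MDP labelled IRF8KO. Per the labels, the cells were enriched on magnetic columns and then sorted by flow cytometry. Groups were taken from the sample titles. The cell type field of the LMPP libraries named short-term hematopoietic stem cells, whereas their titles, the series design text and the sorted surface markers (CD117+ Sca-1+ CD135+) named LMPP, and the titles were followed. The design text calls the wild-type libraries of a cell type biological duplicates. No label says which animals a library came from, and the design text does not name the knockout libraries.

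Each library came with its own peak list. Per the submitters' processing notes, Bowtie 1.1.2 and HOMER 4.9 were used, with the mouse builds mm10 and GRCm38 named. Per the file headers, HOMER called peaks in each library by itself with no control library, a starting peak size of 500 bp, a minimum distance of 1000 bp between peaks, a false discovery rate of 0.001, at least 4-fold enrichment over the local surroundings and at most 1 tag counted per base pair. The same settings stood in all 10 headers. The headers also gave the total tags and the percent of tags within peaks. Whether reads were shifted for the transposase's cut offset is not given in the sources used here. The deposited score column held the value 1 in every row, so it carried no strength. Row order was assumed to follow peak strength, which the lists cannot show. It was reproducible: over regions found in both replicates of a group, the row positions of the replicates had Spearman correlations of 0.883 to 0.946 across regions. Row position within a list was therefore used as the rank of a peak wherever the design called for a score. The lists held positions and no tag counts per peak, so detection was compared, not signal, and no count model was used.

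Peaks on chromosomes 1 to 19 and X of all 10 lists were merged where they overlapped by at least 1 bp, which gave 114366 regions with a median width of 752 bp. A region was detected in a library when a peak of that library overlapped it by at least 1 bp. In a comparison, a region was gained when both libraries of the second group and neither of the first detected it, and lost in the reverse case. Replicate noise in these counts was gauged by the same count for the 2 other ways to split the 4 libraries 2 against 2. These other splits mix the groups, so a difference in depth or quality between groups falls on both sides and is not measured. Strong regions were those in the top 25% of both lists of a group by rank. No blacklist of repeat-rich regions was used here, and the widest merged region spanned 77496 bp.

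Genes came from a RefSeq table of GRCm38.p6, the same assembly as mm10, with 21627 protein-coding genes on these chromosomes. That table gives each gene's start and end without its strand, so transcription start sites were not known. The planned nearest start site was replaced by the nearest protein-coding gene span within 100 kb of the region's centre, with ties going to the nearer gene end. The planned promoter share was replaced by the share of regions within 1 kb of either end of a protein-coding gene. Of the merged regions, 91.4% had a gene within 100 kb. No genome sequence was used here, so the planned motif shares were not run. Coordinates are given 1-based in mm10.

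Before the data were examined, 17 gene lists, the comparisons, the tests, the alternatives and the rule for the genes named in the text were fixed. The lists were stem cell, lymphoid priming, monocyte and macrophage, conventional dendritic cell, plasmacytoid dendritic cell, neutrophil and granule, erythroid, megakaryocyte, mast cell and basophil, B cell, T and NK cell, endothelial and stromal, neuronal, interferon response, antigen processing and lysosome, cell cycle, and housekeeping genes. They held 338 entries of 331 distinct genes, of which 336 entries matched a protein-coding symbol, Ighm and Mx1 being the others. The named genes of a comparison were the 6 with the most net gained and the 6 with the most net lost regions (ties by the larger share of regions changed, then by name), 3 members of each list that passed its test, 7 fixed genes (Irf8, Spi1, Cebpa, Klf4, Gata2, Flt3 and Csf1r), and the genes nearest to the gained and the lost region of highest rank. Some genes that this rule picks are not reported.

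For each list, the gained minus lost regions over its members were compared, two-sided, with 10000 random gene lists of the same size drawn within deciles of regions per gene, with Benjamini-Hochberg adjustment over the 17 lists of a comparison and a threshold of 0.05. Genes entered when at least 1 of their regions was detected in both libraries of either group. Shares carry Wilson 95% intervals, which cover counting error only. Gained and lost regions were compared near gene ends by two-sided Fisher's exact test. Among regions of both WT MDP libraries, those lost and those kept in the knockout were compared for detection at other stages by the Cochran-Mantel-Haenszel test within deciles of WT MDP rank, with p-values floored at 1e-300. The fixed design named peak width for lists without a score. Row position was used in its place after the lists were seen, so the rank deciles are the later choice, and the result within deciles of peak width, as designed, is given beside it. These tests take regions or genes as units, so they describe these libraries. Peaks per library were compared by an exact two-sided permutation test, whose smallest p with 2 against 2 libraries is 0.333, so no such comparison could reach 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

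The procedure was tested on simulated data with detection rates per rank decile taken from the replicates of the second group of a comparison. The simulated libraries of both groups shared these rates, so false calls from unequal depth or quality between groups were not simulated. For WT MDP to IRF8KO MDP, with 48661 regions, 83.5% of 200 regions opened and 84.5% of 200 regions closed by design were recovered and none in the wrong direction, counted as 0, while 676 of 48204 unchanged regions were called gained and 653 lost. A planted list of 20 genes gave a permutation p of 5.0e-04 in that simulation, and 0 of 100 random lists passed 0.05 (0%). In the LT-HSC to LMPP simulation 6.00% of 100 random lists passed. A planted odds ratio of 0.5 was returned as 0.514 (95% interval 0.491 to 0.538) with the rank deciles and as 0.318 without them. Strength acted there only through the same deciles, so this recovery was built in. Differences in strength within deciles, or row order that measures strength poorly, were not simulated.

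Alternatives covered the overlap rule, direct comparison of peaks without merging, the upper 50% of each list, lists trimmed to the shortest in a comparison, autosomes alone, other distances to genes, and leaving out each replicate in turn. Assignment by the nearest gene end was added after the data were seen. Peaks on chromosome Y, the mitochondrial genome and unplaced sequences, 11 to 22 per library, were left out of the comparisons.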

Results

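Open chromatin was mapped by ATAC-seq in 4 wild-type (WT) progenitor stages of mouse bone marrow and in monocyte-dendritic cell progenitors (MDP) lacking IRF8, a transcription factor of the interferon regulatory factor family needed for monocyte and dendritic cell development. In order of development, the WT stages were LT-HSC (long-term stem cells), LMPP (multipotent progenitors primed for lymphoid fates), MDP and CDP (progenitors common to dendritic cells), with 2 libraries per group and 10 in all. Total tags per library ranged from 4790046 to 10166833, per the file headers.

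LT-HSC replicate 1 stood apart in peak number, and the LT-HSC libraries had the lowest percent of tags within peaks. LT-HSC replicate 1 had 31325 peaks with 19.3% of tags within peaks, and replicate 2 had 52147 peaks with 38.1%. LMPP libraries had a mean of 63765 ± 588 peaks (SD, n = 2), WT MDP 63323 ± 1686 (SD, n = 2), CDP 67544 ± 2905 (SD, n = 2) and IRF8KO MDP 52503 ± 2510 (SD, n = 2). Tags within peaks were 52.5% ± 1.76 in WT MDP and 43.8% ± 0.16 in IRF8KO MDP (SD, n = 2 each), at mean totals of 5361548 and 5051888 tags. CDP libraries were sequenced more deeply, with a mean of 9076131 tags. In exact permutation tests, no comparison of peaks per library gave a p below 0.333, the smallest that 2 against 2 libraries allow.

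**Figure D1:**
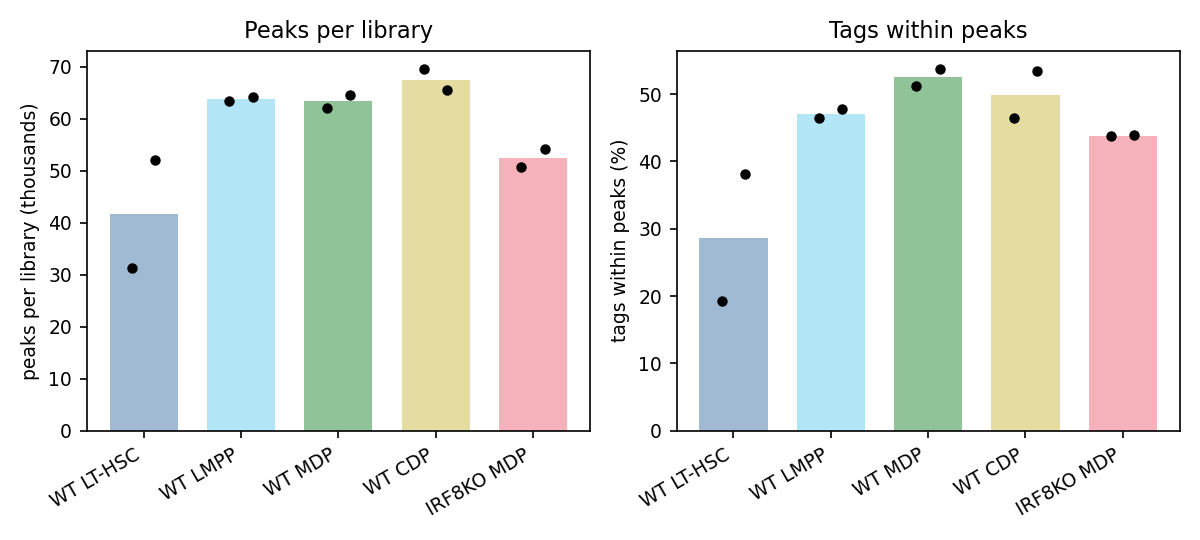
Left, peaks per library, in units of 1000; right, percent of tags within peaks; bars are means of 2 libraries and points are single libraries. LT-HSC replicate 1, with 31325 peaks and 19.3% of tags within peaks, lies below all other libraries.

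Replicates shared more regions with each other than with libraries of other groups, except LT-HSC, where a pair with LMPP reached 0.577 against 0.567 between the replicates. The Jaccard index, the regions found in both libraries over those found in either, was 0.806 between the CDP replicates, 0.772 for WT MDP, 0.766 for LMPP, 0.754 for IRF8KO MDP and 0.567 for LT-HSC. Between groups, it was highest for WT MDP with CDP, at a mean of 0.670 (range 0.666 to 0.675 over 4 library pairs). It was lower for WT MDP with IRF8KO MDP at 0.613 (0.607 to 0.619), LMPP with WT MDP at 0.520 (0.518 to 0.521) and LT-HSC with LMPP at 0.497 (0.418 to 0.577). IRF8KO MDP had a mean of 0.501 with CDP (0.492 to 0.508) and 0.478 with LMPP (0.474 to 0.481).

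The targeted gene, Irf8 (gene 15900, chromosome 8, 120736358 to 120756694), lay among 44 merged regions within 100 kb of its lower-coordinate end. LT-HSC replicates detected 2 and 8 of them, LMPP 13 and 14, WT MDP 29 and 26, CDP 35 and 32, and IRF8KO MDP 21 and 24. The region over that gene end (120735571 to 120737963) was detected in 9 libraries, both knockout libraries included, so the peaks carry no check of the genotype. Regions centred 31.7 kb (120766510 to 120769635) and 56.7 kb (120792222 to 120793816) from the gene end were detected in all 8 libraries of LMPP, WT MDP, CDP and IRF8KO MDP and in neither LT-HSC library. Regions centred at -16.3 kb (120719604 to 120720506) and 41.2 kb (120777007 to 120778069) were detected in both WT MDP and both CDP libraries and in no other library. They were among 4 regions nearest to Irf8 that were lost in IRF8KO MDP, with those at 47.9 and 64.3 kb. A region at 3.4 kb (120739489 to 120740007), inside the gene, was detected in the 2 knockout libraries alone. Of the 44 regions, those centred from -71.5 to -34.2 kb lay nearest to Emc8 or Cox4i1. The counts given for Irf8 as a gene in the comparisons below leave these out.

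**Figure D2:**
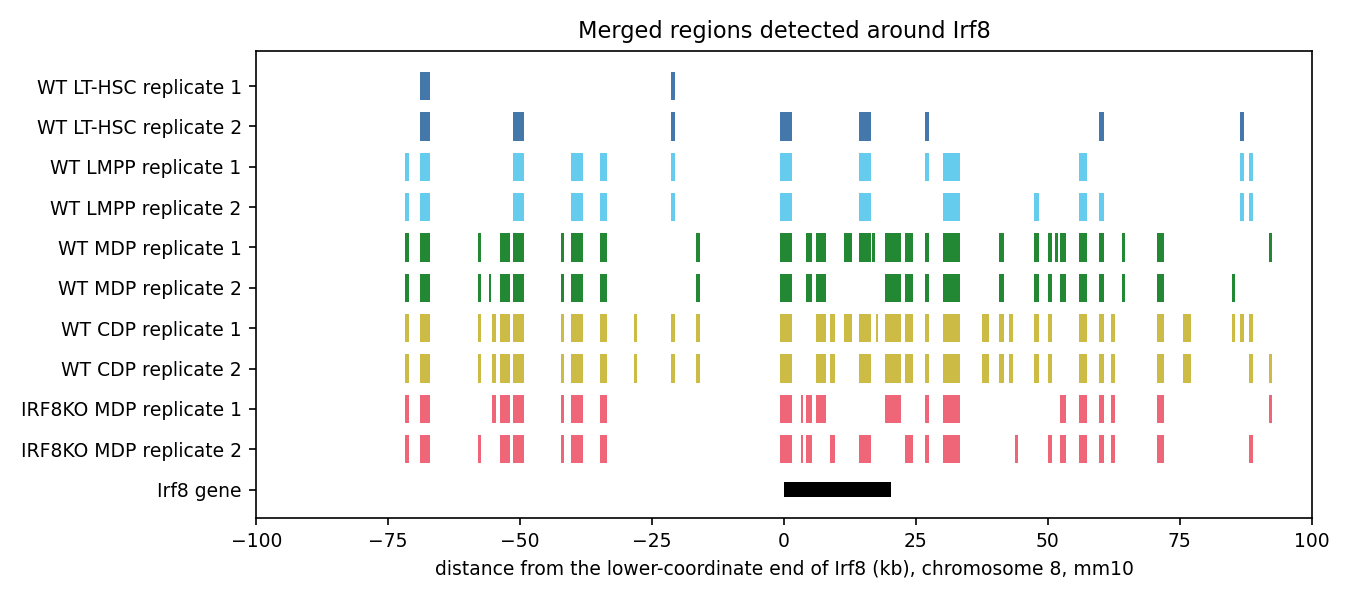
Merged regions detected in each of the 10 libraries around Irf8 on chromosome 8 (mm10); the x axis gives the distance in kb from the lower-coordinate end of the gene, drawn to scale, and the black bar is the gene. WT MDP replicates show 29 and 26 regions, CDP 35 and 32, IRF8KO MDP 21 and 24, and LT-HSC 2 and 8.

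Across the comparisons, regions gained and lost exceeded the counts from the other splits of the same libraries. Those splits gauge replicate noise and not a difference in depth or quality between groups. From LT-HSC to LMPP, 14520 regions were gained and 1852 lost, against at most 1630 in another split. From LMPP to MDP the counts were 11735 and 12125 (at most 680), from MDP to CDP 7406 and 4159 (at most 1140), and over the whole path from LT-HSC to CDP 27507 and 6174 (at most 1274). Between WT MDP and IRF8KO MDP, 3073 regions were gained and 10283 lost (at most 1140). The number lost from LT-HSC to LMPP exceeded the highest other split only narrowly.

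**Figure D3:**
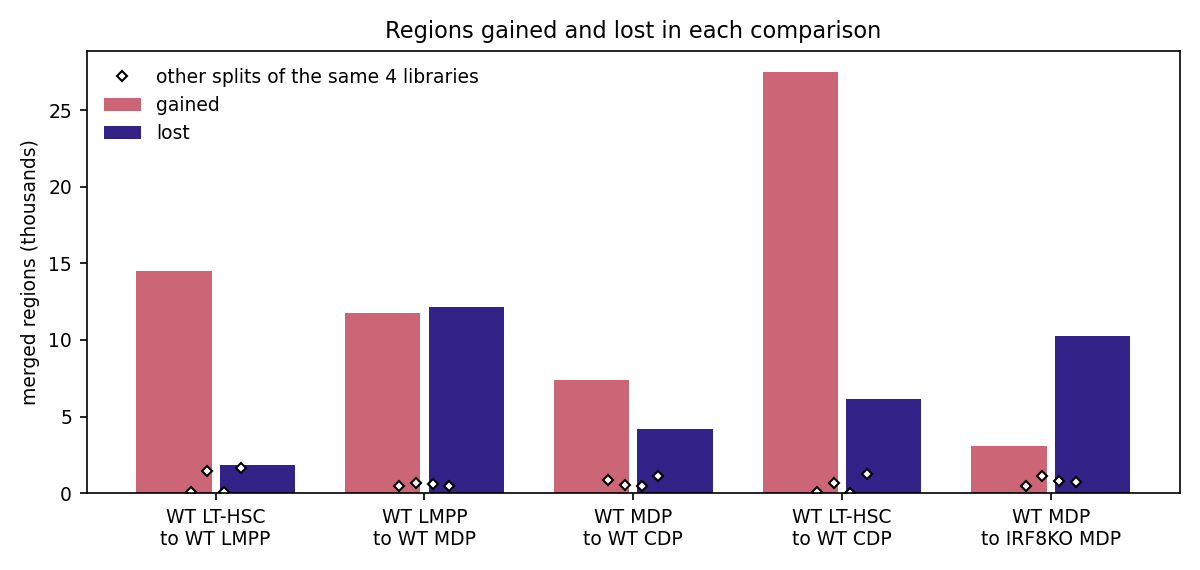
Merged regions, in units of 1000, gained (red) and lost (blue) in each of the 5 comparisons; white diamonds are the counts from the other 2 splits of the same 4 libraries, in both directions. The highest diamonds stand at 1630, 680, 1140, 1274 and 1140 regions, from left to right.

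The first comparison asked what opens and closes between stem cells and lymphoid-primed progenitors. Erythroid genes lost accessible regions from LT-HSC to LMPP while regions elsewhere were mostly gained: 11 of 20 measured members had a net loss, 4 a net gain and 5 neither, and 24 of their 76 regions were lost against 10 gained. Random lists gave a mean net of 19.3 gained regions (95% range 9 to 32) where the erythroid list had a net of -14 (adjusted permutation p = 0.0017). Zfpm1, a cofactor of GATA1, lost 4 of 11 regions. Alas2, the first enzyme of heme synthesis in red cell precursors, and Gata1, the main erythroid transcription factor, each lost both of their 2 regions, with 0 in the other splits. Nprl3, whose introns hold enhancers of the alpha-globin genes, lost 4 of 8 regions (chromosome 11, 32231963 to 32267707).

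Of other genes with the most lost regions in LMPP, Ndst3, a heparan sulfate sulfotransferase, lost 4 of 6, the cadherin gene Cdh11 lost 3 of 3, and Afmid and Cyp4x1 each lost 3 of 4, all with 0 in the other splits. The most net gained regions lay at Snx29, a sorting nexin gene (17 of 33 gained, chromosome 16, 11322861 to 11759095), and Slc9a9, an endosomal sodium-proton exchanger (14 gained of 31), with at most 1 in the other splits. Ctnnd2 gained 14 of 19 and lost 1, Vav3 gained 13 of 24, the transcription factor gene Nfia gained 15 of 49 and lost 2, and Nav2 gained 14 of 44 and lost 1 (up to 3 in another split). The gained region of highest rank (chromosome 7, 55783823 to 55785397) lay 5.2 kb from Siglech, a surface lectin of plasmacytoid dendritic cells. The lost region of highest rank (chromosome 1, 51299774 to 51301137) lay inside Cavin2, a caveolar coat gene. Irf8 gained 3 of 7 regions, and Cebpa (1 of 6), Klf4 (1 of 6) and Csf1r (1 of 3) gained single regions. Spi1 (4 regions), Gata2 (6) and Flt3 (6) had 0 gained and 0 lost.

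No other list passed in this comparison. Lymphoid priming genes had a net gain of 47 regions, with 12 members at a net gain and 0 at a net loss (adjusted permutation p = 0.132). B cell genes had 19, with 9 members at a net gain and 0 at a net loss (permutation, 0.132), cell cycle genes 3 (0.132) and plasmacytoid dendritic cell genes 29 (0.220). Net gains were 43 for stem cell, 28 for monocyte and macrophage, 29 for conventional dendritic cell, 6 for neutrophil and granule, 7 for megakaryocyte, 13 for mast cell and basophil and 13 for T and NK cell genes. They were 14 for endothelial and stromal, 16 for neuronal, 5 for interferon response, 15 for antigen processing and lysosome, and 3 for housekeeping genes, with adjusted p from 0.390 to 0.942. Gained regions lay within 1 kb of a gene end in 5.87% of cases (Wilson 95% interval 5.50 to 6.27), and lost regions in 7.18% (6.09 to 8.45), against 40.3% (39.7 to 40.9) of regions shared by all 4 libraries; gained against lost p = 0.0293 by Fisher's exact test. Gained minus lost was -1.31 percentage points, -2.22 within 2.5 kb and -11.0 at equal list lengths (Fisher's exact p = 6.8e-63). With lists trimmed to equal length, the counts came to 4940 gained and 3972 lost, and 4 lists passed, 3 of them besides erythroid genes. Net changes above random lists were 18.6 for lymphoid priming (adjusted permutation p = 0.0042; range over all settings 0.0025 to 0.394), -10.2 for megakaryocyte (0.0323; 0.0323 to 0.873) and 7.43 for B cell genes (0.0489; 0.0489 to 0.394). Without LT-HSC replicate 1, 7730 regions were lost and lymphoid priming genes passed (permutation, 0.0442), and without LT-HSC replicate 2, 26969 were gained. Without LMPP replicate 1, lymphoid priming (0.0025) and plasmacytoid dendritic cell genes (0.0119; range 0.0119 to 0.883) passed.

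From LMPP to MDP, the step at which lymphoid potential is left behind, 76 of 213 regions at stem cell genes were lost and 16 gained. Of 26 measured members, 12 had a net loss, 4 a net gain and 10 neither, and the net of -60 compared with -0.217 for random lists (95% range -22 to 20; adjusted permutation p = 8.5e-04). Mecom, a transcription factor needed for stem cell self-renewal, lost 21 of 33 regions and gained 0 (chromosome 3, 29951296 to 30509759; other splits 0). Meis1, a homeobox partner of HOX proteins, lost 10 of 25, and Prdm16 lost 10 of 18 and gained 1. From LT-HSC to LMPP, stem cell genes had gained 52 of 202 regions and lost 9. Mecom had gained 11 of 33, Meis1 7 of 25 and Prdm16 6 of 17. Mecom had only 12 regions detected in both LT-HSC or both CDP libraries, so some of the 21 lost by MDP were not detected in both LT-HSC libraries. The same may hold at other stem cell genes, which was not checked region by region.

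Myeloid genes of 3 lists gained regions at this step. Neutrophil and granule genes gained 25 of 64 regions and lost 2, with 16 of 21 members at a net gain (net 23, random range -10 to 11; adjusted permutation p = 8.5e-04). Among them were Ctsg, a granule protease (4 of 4), Csf3r, the receptor for granulocyte colony-stimulating factor (3 of 5), and the lactoferrin gene Ltf (3 of 5). Conventional dendritic cell genes gained 43 of 162 regions and lost 12, with 18 of 26 members at a net gain (net 31, random range -20 to 21; adjusted permutation p = 0.0289). Among them were Irf8 (10 gained and 3 lost of 20), the inhibitory receptor gene Btla (3 of 7) and Sirpa, a marker of one dendritic cell subset (3 of 7). Monocyte and macrophage genes gained 45 of 169 and lost 15, with 17 of 28 members at a net gain (net 30, random range -21 to 22; adjusted permutation p = 0.0323). Among them were F13a1 (5 of 10), the Fc receptor gene Fcgr3 (4 of 6) and Ly6c2, a surface marker of inflammatory monocytes (3 of 6). None of these examples but Irf8 lost a region. Counting only regions over 1 kb from a gene end, the adjusted permutation p was 0.0537 for the neutrophil (range over all settings 8.5e-04 to 0.0537), 0.0537 for the conventional dendritic cell (0.0068 to 0.0537) and 0.0541 for the monocyte list (0.0068 to 0.0847), so these calls ended. The net above random lists was then 13.04, 24.3 and 24.3 regions, against 22.1, 30.1 and 29.2 with all regions. The monocyte list also missed the threshold with genes assigned within 20 kb (0.0847, at 21.2 regions) and without WT MDP replicate 2 (0.0684, at 29.4 regions).

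Of single genes, Tpcn2, a lysosomal cation channel, gained 10 of 17 regions from LMPP to MDP, Runx1, a transcription factor of blood formation, gained 11 of 28 and lost 1, and Sgip1 gained 11 of 21 and lost 2. Nedd9, a scaffold of focal adhesions, gained 9 of 17, Tgfbr2, a receptor for transforming growth factor beta, gained 10 of 24 and lost 1, and Pparg, a lipid-sensing nuclear receptor, gained 8 of 12. Besides Mecom, the most lost regions lay at Nrxn3 (17 of 27, 2 gained), the Slit receptor gene Robo1 (13 of 15), Plxdc2 (14 of 19, 1 gained), the synaptic scaffold gene Dlg2 (18 of 41, 5 gained) and Nfia (16 of 52, 3 gained). For none of these genes did another split exceed 1 region. Spi1, which encodes PU.1, gained 2 of 7, Flt3 gained 2 of 9, Cebpa gained 1 of 7 (1 in another split), Klf4 gained 1 and lost 1 of 7, and Gata2 (6 regions) and Csf1r (3 regions) had 0 changes. The gained region of highest rank (chromosome 2, 73037135 to 73040633) lay 53.9 kb from Ola1, and the lost one (chromosome 1, 42982793 to 42984809) lay inside Gpr45.

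The remaining lists did not pass from LMPP to MDP. Net changes were 18 for cell cycle (adjusted permutation p = 0.0793), -14 for neuronal (0.0793), 14 for antigen processing and lysosome (0.173) and -18 for lymphoid priming genes (0.191). They were -2 for plasmacytoid dendritic cell, -8 for erythroid, -6 for megakaryocyte, 3 for mast cell and basophil, -7 for B cell, 1 for T and NK cell, -4 for endothelial and stromal, 3 for interferon response and 7 for housekeeping genes (0.353 to 1.00). Without LMPP replicate 1, lymphoid priming (permutation, 0.0204), neuronal (0.0215) and cell cycle genes (0.0296) passed, and without LMPP replicate 2, neuronal (0.0258) and cell cycle genes (0.0419) did, where the ranges over all settings were 0.0204 to 0.511, 0.0215 to 1.00 and 0.0296 to 0.621. Gained regions were within 1 kb of a gene end in 6.05% (5.63 to 6.50), lost ones in 6.67% (6.24 to 7.13) and shared ones in 31.5% (31.0 to 31.9; gained against lost p = 0.0497, Fisher's exact test). Within 2.5 kb, the sign turned, with gained regions 1.90 percentage points above lost ones (Fisher's exact p = 6.3e-06).

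From MDP to CDP, which restricts potential to dendritic cells, no list passed in the permutation test against random lists, and 4 lists had an unadjusted p under 0.05. Conventional dendritic cell genes had 34 regions gained and 5 lost of 201, with 13 of 26 members at a net gain and 0 at a net loss (net 29, random range -2 to 26; adjusted permutation p = 0.183). Neutrophil and granule genes had 3 gained and 8 lost of 67 (adjusted permutation p = 0.187), B cell genes 11 gained and 1 lost (0.183) and neuronal genes 9 gained and 14 lost (0.183). Trimmed to equal list length, the conventional dendritic cell list passed (adjusted permutation p = 0.0408), and without WT MDP replicate 1 it had 0.0391, over a range of 0.0391 to 0.608 in all settings.

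At single genes, Arhgap26 gained 13 of 44 regions and lost 2 from MDP to CDP (chromosome 18, 38601617 to 39376285). Camk1d, a calcium-dependent kinase gene, gained 9 of 26, Tmcc3 gained 8 of 28 (up to 2 in another split), and Foxp1, a forkhead transcription factor, gained 11 of 65 and lost 3. Arhgap5 gained 7 of 15, and the cytoskeletal linker gene Macf1 gained 8 of 23 and lost 1. Losses were most frequent at Ccser1 (8 of 13), the receptor phosphatase gene Ptprm (7 of 21) and Pam, an enzyme of peptide amidation (7 of 11, 1 gained). They were followed by Ptgdr, a prostaglandin D2 receptor (6 of 10), and Il20rb (6 of 11), with 0 in the other splits. Irf8 gained 8 and lost 3 of 25 regions, Csf1r, the receptor for macrophage colony-stimulating factor, gained 2 of 7, and Flt3, the cytokine receptor CD135, gained 1 of 13. Spi1 lost 2 of 7, Gata2 lost 1 of 6, Klf4 gained 1 and lost 1 of 8, and Cebpa had 0 changes over 7 regions. The strongest gained region (chromosome 11, 45116193 to 45117608) had no protein-coding gene within 100 kb, the nearest being 109 kb away, and the strongest lost region (chromosome 10, 120685854 to 120686913) lay 94.7 kb from Msrb3.

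The other lists had net gains of 1 for stem cell, 18 for lymphoid priming, 16 for monocyte and macrophage, and 7 for plasmacytoid dendritic cell genes. Net gains were 3 for erythroid, 3 for megakaryocyte, 3 for mast cell and basophil, 10 for T and NK cell, 7 for endothelial and stromal, 6 for interferon response, 11 for antigen processing and lysosome, 6 for cell cycle and 5 for housekeeping genes, with adjusted p from 0.374 to 1.00. Of gained regions, 5.51% (5.01 to 6.05) lay within 1 kb of a gene end, of lost regions 8.34% (7.54 to 9.22) and of shared regions 26.6% (26.2 to 27.0; gained against lost p = 5.8e-09, Fisher's exact test). Within 2.5 kb, the difference was -1.25 percentage points (Fisher's exact p = 0.0523). With lists trimmed to equal length, 5968 regions were gained and 4977 lost, against 7406 and 4159 with all peaks. Equal lengths draw these counts together by construction, and CDP libraries were sequenced more deeply than WT MDP. Depth and a difference between groups therefore cannot be told apart for this excess of gains. Without CDP replicate 2, 12599 regions were gained, and 8053, 6999 and 6338 were lost without WT MDP replicate 1, WT MDP replicate 2 and CDP replicate 1. Few strong regions differed: 18 of 15411 regions in the top 25% of both CDP lists were gained and 14 of 14070 in WT MDP were lost. From LMPP to MDP, 357 of 14070 and 564 of 14151 did.

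Over the whole path from LT-HSC to CDP, stem cell genes stood out by a low net gain. They gained 41 and lost 38 of 163 regions, a net of 3 where random lists averaged 61.3 (95% range 36 to 87; adjusted permutation p = 0.0017), with 7 of 25 members at a net loss and 10 at a net gain. Mecom lost 5 of 12 regions, and Hlf, a transcription factor of stem cells, lost 3 of 6. Erythroid genes lost 27 and gained 18 of 79 regions (net -9, random mean 27.1, 95% range 12.0 to 43; adjusted permutation p = 0.0017), with 10 of 19 members at a net loss. Car2, a carbonic anhydrase of red cells, lost 5 of 6, Zfpm1 lost 4 of 12 and gained 1, and Alas2 lost both of 2.

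Foxp1 gained 33 of 60 regions from LT-HSC to CDP and lost 3 (up to 2 in another split; chromosome 6, 98925342 to 99522746), Lpp gained 25 of 39 and lost 1, and Itga9, an integrin chain, gained 22 of 28. Snx29 gained 22 of 38, Sgms1, a sphingomyelin synthase, gained 21 of 34, and Arhgap26 gained 22 of 44 and lost 2. Irf8 gained 17 of 22 regions and lost 0, Flt3 gained 6 of 13, Csf1r 5 of 7, Klf4 4 of 7 and Cebpa 2 of 7, while Spi1 (5 regions) had 0 changes and Gata2 lost 1 of 6. Losses were most frequent at Nav3 (10 of 11), Opcml (10 of 11, 1 gained), Robo1 (9 of 9), Nrxn3 (9 of 10, 1 gained) and Astn2 (7 of 8). For all genes named here but Foxp1, another split gave at most 1 region. The strongest gained region (chromosome 9, 47733337 to 47735146) lay inside Cadm1, an adhesion molecule of cross-presenting dendritic cells, and the strongest lost region (chromosome 18, 9210370 to 9214678) lay 0.3 kb from the Wnt receptor gene Fzd8.

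The other lists had net gains of 113 for conventional dendritic cell (24 of 26 members up, 0 down; adjusted permutation p = 0.0867), 4 for megakaryocyte (0.153), 44 for antigen processing and lysosome (0.176), 28 for B cell (0.209) and 9 for neuronal genes (0.227). Further net gains were 85 for monocyte and macrophage, 33 for T and NK cell, 67 for lymphoid priming, 24 for neutrophil and granule, and 23 for mast cell and basophil genes. They were 42 for plasmacytoid dendritic cell, 40 for cell cycle, 19 for interferon response, 26 for endothelial and stromal and 14 for housekeeping genes (0.331 to 1.00 for these 10 lists). With lists trimmed to equal length, 10409 regions were gained and 8772 lost, a ratio of 1.19 against 4.46 with all peaks. There, 6 lists passed, 4 of them besides stem cell and erythroid genes. Net changes above random lists were -22.1 for neuronal (adjusted permutation p = 0.0017; range over all settings 0.0017 to 0.434) and -16.5 for megakaryocyte genes (0.0204; 0.0204 to 0.223). They were 30.6 for conventional dendritic cell (permutation, 0.0123; 0.0034 to 0.227) and 26.4 for monocyte and macrophage genes (0.0360; 0.0360 to 0.568). Of gained regions, 6.06% (5.78 to 6.34) lay within 1 kb of a gene end, of lost regions 10.2% (9.50 to 11.02) and of shared regions 46.3% (45.7 to 47.0; gained against lost p = 4.7e-29, Fisher's exact test). Gained minus lost was -4.18 percentage points, -1.77 within 2.5 kb and -6.51 at equal list lengths. Without LT-HSC replicate 1, 16385 regions were lost, and the conventional dendritic cell (permutation, 0.0034) and neuronal lists (0.0399) passed.

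**Figure D4:**
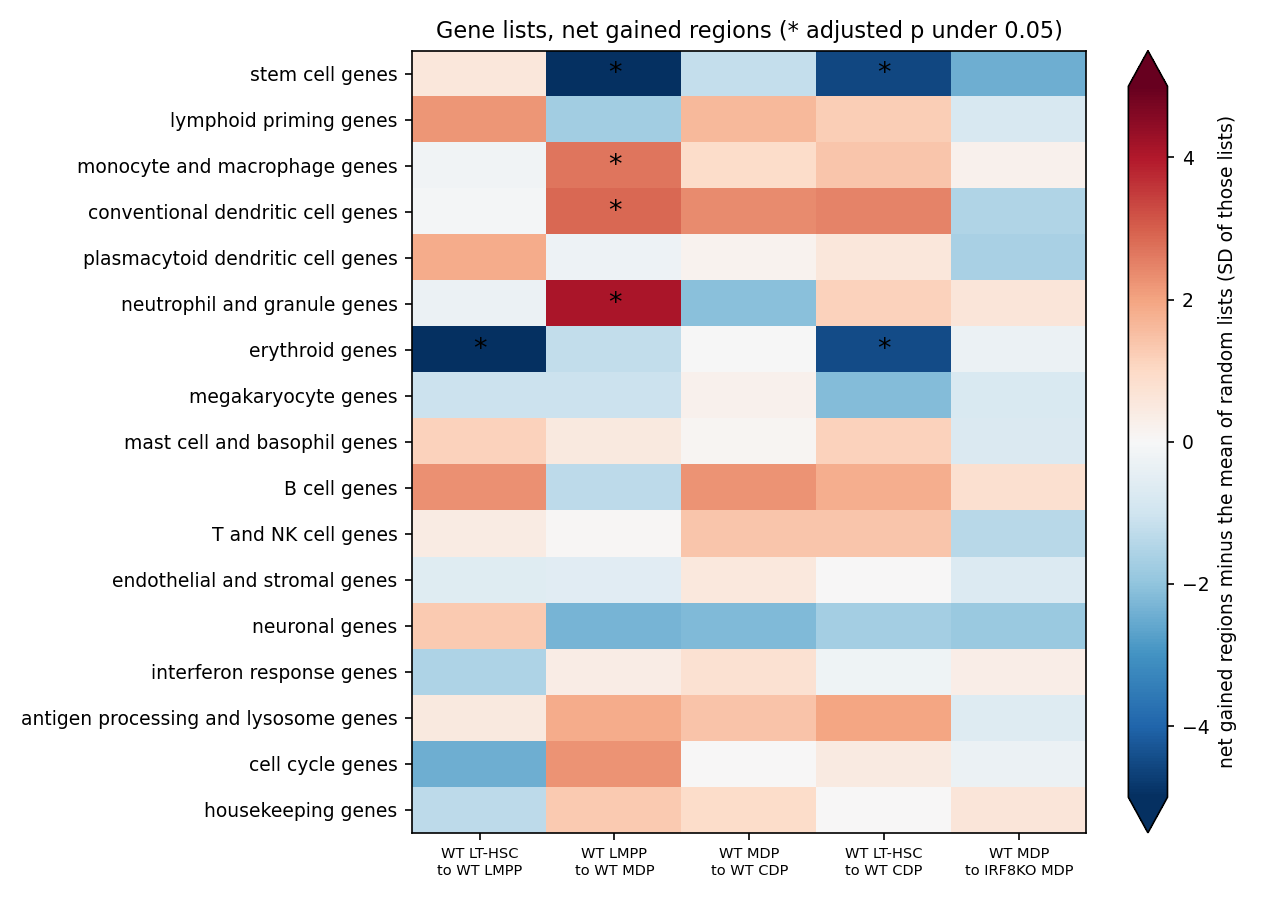
Net gained regions of 17 gene lists (rows) in 5 comparisons (columns), minus the mean of 10000 random lists and in units of their SD; red is net gain, blue net loss, colours saturate at 5, and stars mark adjusted p under 0.05. Stars fall on erythroid genes from LT-HSC to LMPP, on 4 lists from LMPP to MDP, and on stem cell and erythroid genes from LT-HSC to CDP.

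By stage, 53087 regions were detected in both or neither replicate of every WT stage. Of these, 20770 (39.1%, Wilson 95% interval 38.7 to 39.5) were detected at every stage, 5976 (11.3%, 10.99 to 11.5) opened by LMPP and stayed, 7853 (14.8%, 14.5 to 15.1) opened by MDP and stayed, and 5634 (10.6%, 10.4 to 10.9) opened by CDP. Of transient or closing regions, 4739 (8.93%, 8.69 to 9.17) were detected in LMPP alone, and 2563 (4.83%, 4.65 to 5.01) in LT-HSC and LMPP. Others were 1836 (3.46%, 3.31 to 3.62) in MDP alone, 1519 (2.86%, 2.72 to 3.01) in LT-HSC alone, and 779 (1.47%, 1.37 to 1.57) in all stages but CDP. Regions of every stage lay within 1 kb of a gene end in 47.9% of cases, against 5.34% of those opened by MDP and 4.83% of those of LMPP alone. A further 55929 regions, 51.3% of those found in WT, were seen in 1 of 2 replicates of some stage and were left out. At equal list lengths, 1772 regions were opened by LMPP and kept, 3755 by MDP and kept, and 2395 opened by CDP. There, 2973 were detected in LT-HSC alone, 3106 in LT-HSC and LMPP, 2037 in LMPP alone, 1151 in MDP alone and 857 in all stages but CDP.

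The knockout comparison asked which accessible regions of MDP differ without IRF8. IRF8KO MDP lost 10283 regions and gained 3073, and among strong regions, 343 of 14070 regions in the top 25% of both WT MDP lists were lost and 7 of 11618 in the top 25% of both knockout lists were gained, with 0 in the other splits. Slc9a9 lost 12 of 32 regions and gained 0 (chromosome 9, 94669557 to 95230453), Itgb8, an integrin chain that activates transforming growth factor beta, lost 12 of 19 and gained 1, and Ank2, an ankyrin gene, lost 12 of 24 and gained 1 (up to 3 in another split). Pde4d, a cyclic AMP phosphodiesterase, lost 13 of 50 and gained 2, the histone deacetylase gene Hdac9 lost 11 of 26 and gained 2, and Ptprm lost 10 of 26 and gained 1. Gains were led by Ednra, an endothelin receptor (7 of 9, 0 lost; chromosome 8, 77663029 to 77724452), Rhoj (5 of 9), Fbxo16 (4 of 6), Akap12 (4 of 9), Ppp1r21 (4 of 9) and the nuclear envelope gene Syne1 (4 of 16).

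Irf8 itself had 4 regions lost and 2 gained of 18 in the knockout, Gata2 2 lost and 1 gained of 7, and Spi1 1 lost and 1 gained of 8. Cebpa had 1 lost and 1 gained of 8, Klf4 1 lost of 6, Flt3 1 gained of 10, and Csf1r 0 changes over 3. The gained region of highest rank (chromosome 13, 41662313 to 41664090) lay 21.8 kb from Tmem170b. The lost region of highest rank (chromosome 2, 98662028 to 98663083) had no protein-coding gene within 1031 kb. It was detected in 7 of the 8 WT libraries, and a region 3.2 kb away (98666239 to 98667549) ranked between 7 and 48 in all 10 libraries. No list of repeat-rich artefact regions was used here, so whether this region is one was not checked.

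No list passed the permutation test against random lists in the knockout comparison, and 1 had an unadjusted p under 0.05. Stem cell genes lost 38 and gained 6 of 122 regions, with 12 of 24 members at a net loss and 0 at a net gain (net -32, random mean -16.3, 95% range -29 to -4; adjusted permutation p = 0.294). Without WT MDP replicate 2 this list passed (0.0221; range over all settings 0.0221 to 0.309). Conventional dendritic cell genes lost 38 and gained 7 of 149, with 19 of 26 members at a net loss (net -31, random mean -20.1; adjusted permutation p = 0.597). Plasmacytoid dendritic cell genes had a net of -20 with 10 of 18 members at a net loss, neuronal genes -15 and T and NK cell genes -11 (each 0.597). Monocyte and macrophage genes had a net of -19 where random lists averaged -20.7 (0.832). Among markers of cell types outside the gate, the net was -5 for neutrophil and granule, -7 for erythroid, -7 for megakaryocyte, -8 for mast cell and basophil, -2 for B cell and -11 for endothelial and stromal genes. It was -20 for lymphoid priming, -5 for interferon response, -13 for antigen processing and lysosome, -12 for cell cycle and -3 for housekeeping genes (0.791 to 0.829 with the former 6). Gained regions lay within 1 kb of a gene end in 5.14% (4.42 to 5.98), lost in 6.42% (5.96 to 6.91) and shared in 30.8% (30.4 to 31.3; gained against lost p = 0.0089, Fisher's exact test). At equal list lengths the counts were 6462 lost and 4979 gained, and the difference near gene ends turned to 0.473 percentage points (Fisher's exact p = 0.296). Without WT MDP replicate 1, 15533 regions were lost, and 4874, 6702 and 5152 were gained without WT MDP replicate 2, knockout replicate 1 and knockout replicate 2.

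Regions lost in the knockout were seldom detected in LT-HSC. Of the 10283 lost regions, 8.92% (Wilson 95% interval 8.38 to 9.48) were detected in both LT-HSC libraries, against 55.3% (54.8 to 55.8) of the 37408 kept regions and 29.1% of kept regions weighted to the same WT MDP ranks. In LMPP the shares were 35.0% (34.1 to 35.9) of lost regions, 81.0% (80.6 to 81.4) of kept ones and 60.6% at matched rank. In CDP the order turned at matched rank: 81.6% (80.8 to 82.3) of lost regions were detected, against 88.6% (88.3 to 88.9) of all kept regions and 68.5% of rank-matched ones. Within rank deciles, the odds ratio of detection for lost against kept regions was 0.199 (95% interval 0.185 to 0.215) in LT-HSC, 0.291 (0.277 to 0.307) in LMPP and 2.44 (2.27 to 2.62) in CDP. In the Cochran-Mantel-Haenszel test, a chi-square test on regions, p was at the floor of 1e-300 for LT-HSC and LMPP and was 6.8e-133 for CDP. The CDP value depended on how peak strength was matched: it was 1.39 (1.30 to 1.48; chi-square p = 9.4e-24) within deciles of WT MDP peak width, the measure the design named for lists without a score, and 0.569 with no deciles. Without WT MDP replicate 2 it was 1.53.

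**Figure D5:**
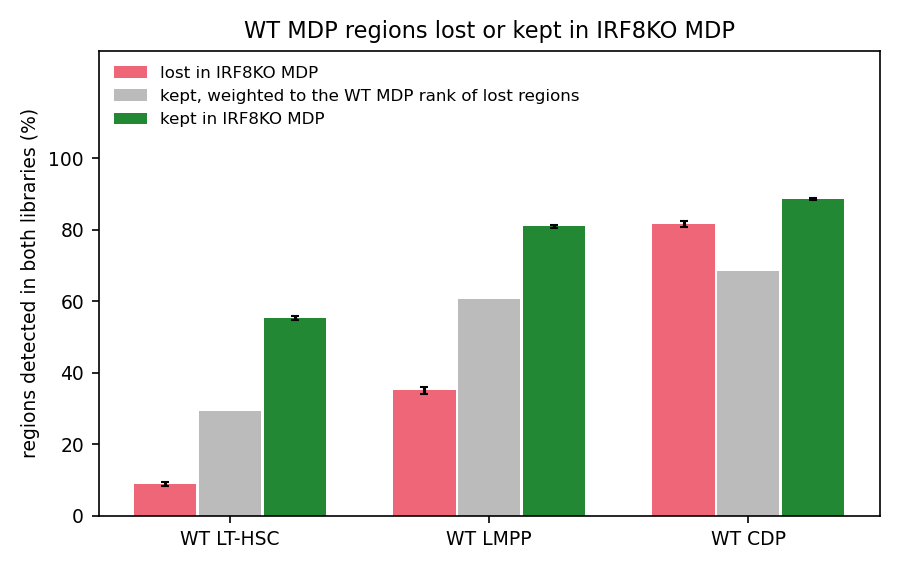
Percent of WT MDP regions detected in both libraries of LT-HSC, LMPP or CDP, for regions lost in IRF8KO MDP (red), kept (green) and kept with weights that match the WT MDP rank of lost regions (grey); error bars are Wilson 95% intervals. Lost regions stand at 8.92%, 35.0% and 81.6%, against 29.1%, 60.6% and 68.5% for rank-matched kept regions.

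Regions gained in the knockout mostly lay outside the WT lists. Of the 3073, 2014 (65.5%, 63.8 to 67.2) were detected in no WT library. Both LT-HSC libraries detected 5.21% (4.48 to 6.05), both LMPP libraries 14.8% (13.6 to 16.1) and both CDP libraries 7.13% (6.27 to 8.09). The 42510 other regions absent from WT MDP had 11.5% (11.2 to 11.8), 27.5% (27.0 to 27.9) and 16.9% (16.5 to 17.3), but most of those entered the merged set through a WT library, which raises their shares by construction. At equal list lengths the shares of gained regions turned in order, with 13.3% in LT-HSC and 5.63% in CDP.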

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

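Counts of peaks on sequences left out of the comparisons were looked at after the peak lists were seen. Peaks on the mitochondrial genome numbered 30, which is 3 in each of the 10 libraries. Peaks on chromosome Y numbered 127 over the 10 libraries, from 8 to 19 per library, and merged into 24 regions, of which 4 were detected in all 10. Both stood out because the comparisons did not use these sequences. No explanation was tested for either.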

How the results depend on the processing

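Settings chosen only after seeing the data were the use of row order as rank, with the rank deciles in place of the designed deciles of peak width, and assignment by the nearest gene end. The latter brought the conventional dendritic cell list past the threshold from LT-HSC to CDP (permutation, 0.0317) and changed no other call. Counting overlaps of 50% changed no region count, because every peak lies inside its merged region, and comparing peaks directly or on autosomes alone left all counts of gained and lost regions within 1.5 times. Motif alternatives were not run. With the upper 50% of each list, gained and lost regions were 7818 and 791 (LT-HSC to LMPP), 6592 and 7068 (LMPP to MDP), 4112 and 2412 (MDP to CDP), 14143 and 2912 (LT-HSC to CDP), and 1715 and 5536 (knockout). With the detecting group at its upper 50% and the other at all peaks, they were 2606 and 286, 2492 and 2707, 498 and 311, 9074 and 1707, and 222 and 2078. At equal list lengths they were 4940 and 3972 from LT-HSC to LMPP and 4979 and 6462 for the knockout, and 10409 and 8772 from LT-HSC to CDP. The larger side was the same in these 3 settings. It turned from LMPP to MDP without WT MDP replicate 1 (16742 gained and 14176 lost) and replicate 2 (15591 and 14742), where fewer MDP libraries have to detect a gain. Leaving out a replicate loosens the rule, so counts rose: gained 14917 to 26969 and lost 2221 to 7730 (LT-HSC to LMPP, most without LT-HSC replicate 2 and 1), gained 10108 to 12599 and lost 5329 to 8053 (MDP to CDP, over 1.5 times without CDP replicate 2, and without either WT MDP or CDP replicate 1), lost 6597 to 16385 (LT-HSC to CDP, most without LT-HSC replicate 1), gained 4215 to 6702 and lost 12303 to 15533 (knockout, over 1.5 times without WT MDP replicate 2 or either knockout library, and without WT MDP replicate 1). The difference in peaks from LMPP to MDP, -442.5, ran from -1635 to 750 and reversed without WT MDP replicate 1. Stage patterns at equal lengths were 3755 opened by MDP and kept, 1772 by LMPP and kept, 2395 by CDP, 2037 LMPP alone and 2973 LT-HSC alone. Replicate overlap fell to 0.592 with peak centres within 200 bp. Near gene ends, gained minus lost was -2.22 points within 2.5 kb and -11.0 at equal lengths from LT-HSC to LMPP (-1.31 as reported), and -1.77 and -6.51 from LT-HSC to CDP (-4.18 as reported). It was 1.90 points within 2.5 kb (reversed) and -0.597 at equal lengths (exact p = 0.0637) from LMPP to MDP, -1.25 within 2.5 kb from MDP to CDP, and -0.251 within 2.5 kb and 0.473 at equal lengths (reversed) for the knockout; the cause was not tested. Lists called at equal lengths numbered 4 (LT-HSC to LMPP), 1 (MDP to CDP) and 6 (LT-HSC to CDP), and 1 from LMPP to MDP over 1 kb from gene ends. With a replicate left out they ran from 1 to 3, 3 to 7, 0 to 1, 2 to 4 and 0 to 1 for the 5 comparisons in that order, the knockout last. For single lists, 21 settings brought a list past the threshold and 5 ended a call. The CDP odds ratio of lost regions was 0.569 without rank deciles, since lost regions rank lower in WT MDP, and 1.39 within the designed deciles of peak width. In LT-HSC and LMPP it stayed under 1 in every setting run. Of regions gained in the knockout, 13.3% were in LT-HSC and 5.63% in CDP at equal lengths over all libraries. No pairing by replicate number was seen in detection: differences between replicates 1 and 2 correlated at -0.016 to 0.013 across regions between groups. A pairing that leaves no trace in detection is not excluded, since no label says which animals a library came from. With a replicate block, the difference in peaks was unchanged (22029 from LT-HSC to LMPP, exact sign-flip p = 0.5, the smallest possible). LT-HSC replicate 1 had the shortest list and 19.3% of tags in peaks, so a weak region missing from it is not shown to be closed.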

Other observations

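The tests of explanations in this part were chosen only after the result was seen, although the equal list lengths and an odds ratio stratified by peak width, not by rank, had been planned. Loss in the knockout differed with the stages at which a region was detected, without a single direction for regions that CDP kept. Of the regions detected at every WT stage, 2.65% (Wilson 95% interval 2.44 to 2.88; 551 of 20770) were lost in IRF8KO MDP. The share was 25.4% (24.3 to 26.5) of the 5976 regions opened by LMPP and kept, and 56.6% (55.5 to 57.7) of the 7853 opened by MDP and kept in CDP. Regions detected in MDP alone were lost less often, at 22.5% (20.6 to 24.5; 413 of 1836), although they ranked lower in WT MDP (median rank at 75.4% of the list, against 61.5%), and those of LMPP and MDP alone at 19.7% (16.5 to 23.4). The order turned for early regions: those detected at every stage but CDP were lost in 24.65% of cases (21.8 to 27.8; 192 of 779).

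For the 10283 regions lost and 3073 gained in IRF8KO MDP, lower library quality would take the weaker peaks first, and regions of every stage but CDP (median rank 71.5%) were lost more often than those of every stage (19.7%), at 24.65% against 2.65%. Regions of MDP alone, weaker than those opened by MDP and kept in CDP, were lost less often, at 22.49% against 56.6%. This argues against quality as the whole cause of which regions were lost, but not as a part of it. At equal list lengths, the ratio of lost to gained fell from 3.35 to 1.30, though equal lengths draw these counts together by construction. For that ratio over all regions, quality and a difference between groups cannot be told apart. Among regions of the 10000 strongest peaks of both libraries of a group, the imbalance remained at equal list lengths. There, 95 of 8864 such WT MDP regions were lost and 4 of 8926 such knockout regions were gained. Of the 10000 strongest peaks of a WT MDP library, 1.32% to 1.85% of regions were missing in a knockout library, against 0.07% to 0.14% in reverse. Of LT-HSC replicate 2, 0.25% were missing in replicate 1, a pair further apart in tags within peaks (38.1% and 19.3%) than WT MDP and knockout (means 52.5% and 43.8%). Of LMPP, 1.20% to 1.51% were missing in LT-HSC replicate 2, and 0.67% to 0.93% in reverse, but these groups also differ in cell type. The benchmark within a group rests on 1 library pair, so these shares do not separate quality from a difference between groups. Other cell types in the knockout gate remain open, since the only lists of other types with a net above random lists had an adjusted p of at least 0.791, which excludes nothing. A direct or indirect dependence on IRF8 is the biological explanation that the IRF8KO label raises. It was not tested here and stays a hypothesis.

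Many more regions were gained than lost from LT-HSC to LMPP. The LT-HSC libraries had the lowest shares of tags in peaks, and at equal list lengths the ratio of gained to lost fell from 7.84 to 1.24, but equal lengths draw these counts together by construction. Lower quality of the LT-HSC libraries and an opening of chromatin therefore cannot be told apart for the ratio over all regions. Among regions of the 10000 strongest peaks of both libraries, at equal list lengths, 225 were gained and 125 lost.

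The late-opening pattern of regions lost in the knockout could come from weak peaks, which any other library misses. Within deciles of WT MDP rank, lost regions would then be detected less often at every stage, but the odds ratio in CDP was 2.4389, with an interval above 1, and 1.39 (1.30 to 1.48) within the designed deciles of peak width. Weak peaks alone therefore do not account for the pattern, although its size depends on the measure of strength. Regions that open late and depend on IRF8 are a candidate explanation for these libraries, with no test of IRF8 binding here.

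A hypothesis was that neighbouring regions close together in the knockout. Of adjacent WT MDP regions within 20 kb, 1482 pairs were both lost, 1.228 times the mean of 1207 (95% range 1152 to 1264) when losses were permuted within rank deciles and gene-end classes (p = 1.0e-03, the smallest that 1000 permutations can give). The ratio was above 1 for gained and lost regions of all 5 comparisons, from 1.13 to 2.43, so the pattern may not be particular to IRF8.

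A further hypothesis was that knockout cells in the MDP gate may keep regions that normally close between LMPP and MDP. Of those 12125 regions, 3.75% (3.43 to 4.11) were detected in both knockout libraries and 11.8% (11.2 to 12.4) in either. Most of them were thus not detected in the knockout lists. The 50% set for retention could not be reached for both libraries, because such regions are all among the 3073 gained in the knockout. That threshold therefore decides nothing. For comparison, 2.96% (2.59 to 3.37) of the 7406 regions that open between MDP and CDP were detected in both. That share is bounded by the same 3073 regions, but the sets differ in size. The highest possible shares therefore differ, and the shares are not on the same scale.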
